A study of Mus musculus with 8 samples.

How the data were processed

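Gene expression was measured with 1-colour Illumina mouse bead arrays in epithelial cells freed from dissected mouse colons with EDTA, a chelator that loosens the epithelium from the tissue beneath it. The mice were C57BL/6 animals kept in gnotobiotic isolators, per the labels. They had been left germ free, colonized with Bacteroides uniformis, a member of the Bacteroidetes, or colonized with a consortium of Clostridia. Groups were taken from the source name of each sample, which gave 2 germ free arrays, 3 B. uniformis arrays and 3 Clostridia arrays. Replicates were numbered in accession order, so the numbers pair no arrays. The labels do not say whether the arrays came from separate animals or from pooled animals, so the p-values measure the spread between these samples, which may be technical.

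The deposited table of non-normalized values gave a signal intensity and a detection p-value for each of 25697 probes on each array. Per the labels, total RNA was labelled with biotin, and BeadStudio, the array maker's software, is the tool named in the submitters' processing notes, with no version. Per the file headers, each detection p-value column follows the intensity column of its array. Each detection p-value column also ran against the intensity of its own array (rank correlation -0.985 to -0.978) more closely than against that of any other array. A table of the authors' normalized intensity values was deposited as well. Its values lay on a linear scale, had the same median (3.7) on each array and reached below 0. They ranked the probes as the raw intensity of the same array did (Spearman correlation at least 0.999977). Background subtraction and quantile normalization by the authors can therefore be read from the values, but the authors' own statement of them, and their test, are not given in the sources used here. The values of this table were used as an alternative.

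Intensities were background corrected, quantile normalized and put on the log2 scale with the neqc function of limma 3.58.1 in R 4.3.3. Negative control levels were inferred from the detection p-values, and an offset of 16 was added, which shrinks the fold changes of dim probes. Probes were named through an annotation table of the array. It gave 1 gene symbol for 23978 probes, several for 0 probes and none for 1719 probes, and 23962 probes were matched by Entrez identifier to a RefSeq gene table of mouse assembly GRCm38.p6, which changed 0 symbols. No coordinates were used. A probe was kept when its detection p-value was under 0.05 on at least 2 arrays, which left 12481 probes, of which 11748 were named and 733 were unnamed. Each gene was represented by its named probe with the highest mean level, which gave 9103 genes, 2054 of them with more than 1 probe past this filter.

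A linear model with 1 mean per group was fitted to all 8 arrays with limma (lmFit and eBayes), so that the 3 groups shared 1 estimate of the spread, with 5 residual and 3.44 prior degrees of freedom. All tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. A moderated F test on the same fit asked whether any group differed. For 33 gene lists of pathways and cell types, limma's camera compared the genes of a list with all other genes, at a preset correlation of 0.01 between genes, and p-values were adjusted over the 29 lists with at least 5 tested members. The same test with an estimated correlation and limma's fry were run beside it. The fry test asks whether the genes of a list move one way on balance, or change in either direction, and does not compare them with other genes. The lists, the named genes, the tests and most alternatives were chosen before the data were examined.

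Genes were named by a fixed rule. Per comparison it took the 12 genes with the largest positive and the 12 with the largest negative change among those past the threshold whose arrays did not overlap between the groups, or the 5 of smallest p in a direction where fewer than 5 passed. It added up to 4 members of each list that passed, at most 2 of any other list and a fixed panel of epithelial defence and metabolism genes. Of that panel, Muc2 had no named probe, and Duox2, Nos2, Tslp and Il25 did not pass the detection filter. A gene not detected on any array of 1 group has only a bound there. Its fold change is given as at least the brighter group's mean over the mean, per array, of the higher of the lowest detected signal and the probe's own signal.

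The pipeline was tested on simulated data with the real residual spread of each gene, drawn independently for each gene. Simulated genes were thus not correlated, while real ones were (estimated correlation 0.558 within the list of T cell markers). The recovery and the false calls do not cover such correlation. With 200 genes changed at once, 34% of genes changed 2-fold and 80% of those changed 4-fold were recovered between Clostridia and germ free. The shares were 36% and 78% between B. uniformis and germ free, and 52% and 90% between Clostridia and B. uniformis. Of the 139, 147 and 165 genes called, 6, 10 and 8 were unchanged genes. With no gene changed, 0 genes were called in each comparison, and a list shifted by -1 was found in each. With an estimated correlation that shifted list was missed between Clostridia and B. uniformis and found in the other comparisons. The alternatives covered the background correction, the between-array normalization, the authors' values, the detection filter, the variance model, array weights, the choice of probes, the threshold, the samples in the fit and each array left out in turn. Covariates for a sex-linked transcript and for T cell markers, a test over the genes of the lists alone and the simulated overlap of genes were added after the data had been seen. The agreement of both colonization effects was set beside 100 simulations of unchanged groups that shared the germ free arrays. Signal over background was modest: the upper quartile of raw intensity was 1.32 to 1.66 times the background on the 8 arrays. The number of arrays limits the precision.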

Results

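The transcriptome of colonic epithelial cells was profiled in 3 groups of gnotobiotic mice: germ free (n = 2 arrays), colonized with B. uniformis (n = 3) and colonized with a Clostridia consortium (n = 3). The series asks how commensal bacteria bear on sensitization to food allergens, and the arrays ask what each colonization does to the epithelium. Each array detected between 10328 and 11291 probes, or 40.2% to 43.9% of all probes. Correlations between arrays ranged from 0.953 to 0.983 across genes. The median correlation was 0.965 for arrays of the same group and 0.968 for arrays of different groups, so the groups did not separate on all genes. The largest principal component held 28.6% of the variance and parted germ free array 1, B. uniformis arrays 1 and 2 and Clostridia array 1 (-19.4 to -14.9) from the other 4 arrays (6.09 to 23.3). Levels are given as log2 normalized signal.

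The Clostridia consortium was compared with germ free mice to ask which epithelial genes differ with this colonization. Cyp2c55, a cytochrome P450 monooxygenase, stood at 12.06 ± 0.48 (SD, n = 3) with Clostridia and at 9.81 ± 0.19 (SD, n = 2) without bacteria, a difference of 2.25 ± 0.27 (SE), or 4.75-fold. Reg3b, an antibacterial C-type lectin of the gut epithelium, stood at 8.21 ± 0.46 (SD, n = 3) against 6.61 ± 0.09 (SD, n = 2), a difference of 1.61 ± 0.26 (SE). Mcpt1, a protease of mucosal mast cells, was detected on both germ free arrays at 5.68 ± 0.08 (SD, n = 2) and on none of the 3 Clostridia arrays, which makes it at least 2.25-fold lower with Clostridia. Its fitted difference depended on the background handling, from -0.44 with no background correction to -4.28 with the authors' values. Cma1, another mast cell protease, was lower by -0.96 ± 0.27 (SE). It stood between 4.86 and 5.019 on the Clostridia arrays and was as low on B. uniformis array 3 (4.848). The list that holds Mcpt1 and Cma1 had only 3 tested members. These 4 genes passed when adjusted over the list alone, with limma adjusted p = 0.000649 for Cyp2c55, 0.00364 for Reg3b, 0.000134 for Mcpt1 and 0.0106 for Cma1. Adjusted over the 429 tested genes of all lists together, Cyp2c55, Mcpt1 and Reg3b passed and Cma1 did not (limma adjusted p = 0.505).

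**Figure D1:**
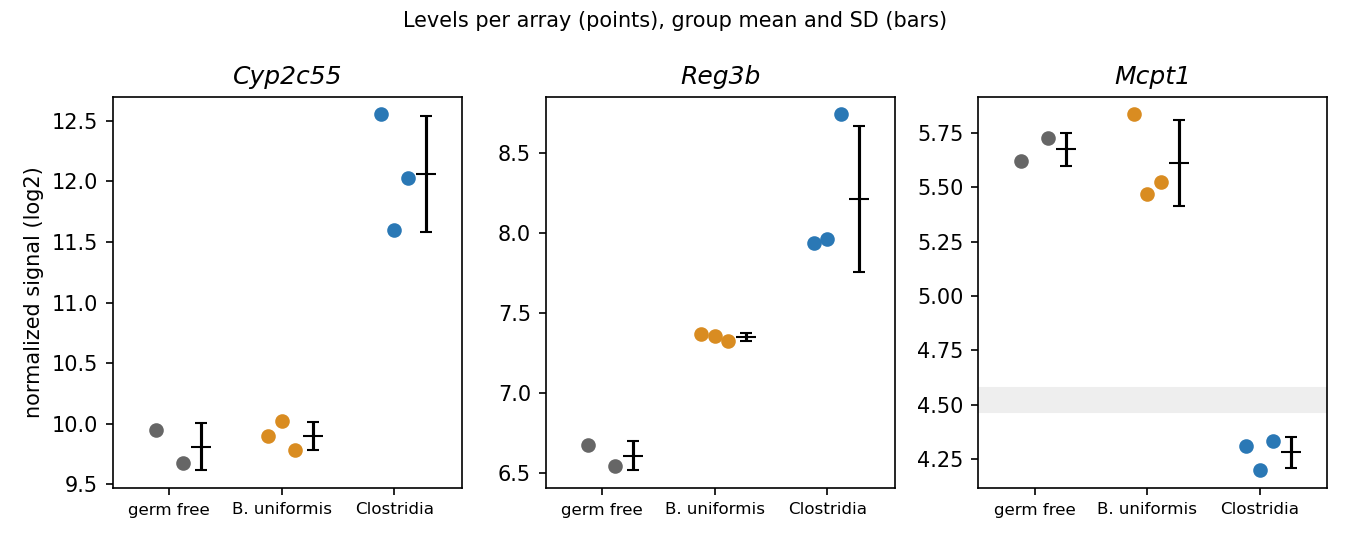
Normalized log2 signal of Cyp2c55, Reg3b and Mcpt1 on each array (points, by group) with the group mean and SD (bars); the grey band spans the lowest detected signal of the arrays, 4.46 to 4.57. Cyp2c55 lies between 11.6 and 12.55 on the Clostridia arrays and between 9.67 and 10.02 on the other 5, and Mcpt1 lies below the band on the Clostridia arrays alone.

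Adjusted over all 9103 genes, limma called 0 genes between Clostridia and germ free, with the smallest adjusted p at 0.203 for Cyp2c55 and Mcpt1. At an unadjusted p under 0.05 there were 382 genes, 211 higher and 171 lower, where 455 are expected by chance. With median scaling they were 229 higher and 86 lower, and without Clostridia array 1 they were 259 higher and 337 lower. The arrays of the groups did not overlap for 18.6% of genes, and chance gives 20%. After Cyp2c55 and Reg3b, the smallest p among higher genes belonged to Depp1, a target of FOXO transcription factors (1.44 ± 0.25 SE), the collagen gene Col16a1 (1.33 ± 0.24 SE) and 4931406C07Rik (0.91 ± 0.17 SE). Among lower genes they belonged, after Mcpt1, to the sodium channel gene Scn11a (-1.26 ± 0.21 SE), the lipid phosphatase gene Plpp1 (-1.03 ± 0.19 SE), the calcium channel regulator gene Cracr2a (-0.96 ± 0.19 SE) and the immune activation marker Cd83 (-1.33 ± 0.28 SE). Limma adjusted p for these 7 genes ranged from 0.522 to 0.868, so none passed. Scn11a lay below the lowest detected signal on Clostridia arrays 2 and 3 (4.141 and 4.199). Its fitted difference ranged from -3.93 to -0.416 over the alternatives. Tlr2, the receptor for bacterial lipoproteins, was measured at 0.76 ± 0.28 (SE), the epithelial cytokine Il18 at 1.26 ± 0.56 (SE) and the intestinal hormone gene Guca2b at -0.82 ± 0.21 (SE), also without passing. Reg3g was measured at 0.49 ± 0.33 (SE), Ang4 at 0.08 ± 0.93 (SE), Retnlb at -0.08 ± 0.60 (SE), Fut2 at 0.24 ± 0.39 (SE) and Il33 at 0.26 ± 0.29 (SE).

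With Clostridia, 4 of the 29 tested gene lists shifted against germ free by camera. Genes of fatty acid oxidation and PPAR targets rose as a group, by a mean of 0.23, with 16 of 19 members higher (adjusted p = 0.0252, and adjusted p = 0.557 with an estimated correlation). Its leading members were Pdk4, a kinase that restrains pyruvate oxidation (1.22 ± 0.30 SE), Angptl4, a secreted inhibitor of lipoprotein lipase (0.86 ± 0.26 SE), the lipid droplet protein gene Plin2 (0.52 ± 0.17 SE) and the mitochondrial carnitine carrier gene Slc25a20 (0.50 ± 0.27 SE). Slc25a20 stood at 10.47 and 9.75 on germ free arrays 1 and 2 and between 10.33 and 10.81 with Clostridia. Genes of the AhR, PXR and CAR xenobiotic response rose by a mean of 0.22 (median 0.09), with 19 of 24 members higher (adjusted p = 0.0462, and adjusted p = 0.77 with an estimated correlation). Cyp2c55, at 2.25, raised this mean well above the median, and the list was not tested without it. Besides Cyp2c55 the list was led by the glucuronosyltransferase gene Ugt1a6a (0.59 ± 0.22 SE) and the glutathione transferase genes Gsta4 (0.54 ± 0.22 SE) and Gsta3 (0.75 ± 0.34 SE). Gsta3 stood at 6.06 and 7.05 on germ free arrays 1 and 2 and between 6.82 and 7.62 with Clostridia. Goblet cell genes fell by a mean of 0.25, with 10 of 12 members lower (adjusted p = 0.0462, and adjusted p = 0.77 with an estimated correlation). Against the mean of the 5 arrays without Clostridia the goblet list stood at -0.483, 0.003 and -0.019 on Clostridia arrays 1, 2 and 3, and without array 1 its mean was -0.09. Members that fell included Spink4 (-0.58 ± 0.24 SE), the goblet cell stress sensor gene Ern2 (-0.43 ± 0.22 SE), the goblet cell transcription factor gene Spdef (-0.73 ± 0.40 SE) and Muc4 (-0.33 ± 0.21 SE). Clca1 was 1 of the 2 members that rose. It stood at 11.90, 12.71 and 13.26 on Clostridia arrays 1, 2 and 3 and at 12.33 and 12.32 on germ free arrays 1 and 2. No member of these lists other than Cyp2c55 passed on its own.

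Markers of T cells and intraepithelial lymphocytes fell with Clostridia by a mean of 1.12, with 14 of 15 members lower (camera adjusted p = 1.63e-07, and adjusted p = 0.77 with an estimated correlation). The integrin gene Itgae was measured at -1.87 ± 0.77 (SE), the T cell receptor chain gene Cd3g at -1.49 ± 0.65 (SE), Cd8b1 at -1.41 ± 0.48 (SE) and Cd7 at -1.09 ± 0.45 (SE), none of which passed on its own. Against the mean of the 5 arrays without Clostridia, the list stood at 0.105 on Clostridia array 1, -1.242 on array 2 and -1.927 on array 3, while those 5 arrays ranged from -0.327 to 0.324. The Y-linked transcript Eif2s3y was not detected on Clostridia arrays 2 and 3 (4.17 and 4.25) and was detected on the other 6 arrays (7.2 to 8.97). Other Y-linked transcripts, near the lowest detected signal, did not follow it. Uty was detected on Clostridia arrays 2 and 3 (4.86 and 4.99) and not on B. uniformis array 2 (4.45), where Eif2s3y was highest (8.97). Kdm5d was not detected on any Clostridia array or on B. uniformis array 3 and was detected on the other 4. Red blood cell markers stood 3.467 above those 5 arrays on Clostridia array 1 and -0.123 and -0.392 on the others. Of the other cell types, myeloid markers averaged -0.50 (7 of 8 lower, camera adjusted p = 0.0533) and stromal markers -0.37 (median -0.17, 4 of 5 lower, adjusted p = 0.349), and endothelial markers averaged 0.01 (3 of 6 higher, adjusted p = 0.925). Thy1 is a member of both the stromal and the T cell list, and stood at 8.967, 6.507 and 5.984 on Clostridia arrays 1, 2 and 3. On the same arrays the myeloid list stood at 0.074, -0.555 and -0.909 and the stromal list at 0.138, -0.582 and -0.704. Both were thus low on arrays 2 and 3 only, like the T cell list. Immediate early and dissociation stress genes averaged 0.19 (16 of 20 higher, camera adjusted p = 0.0639).

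**Figure D2:**
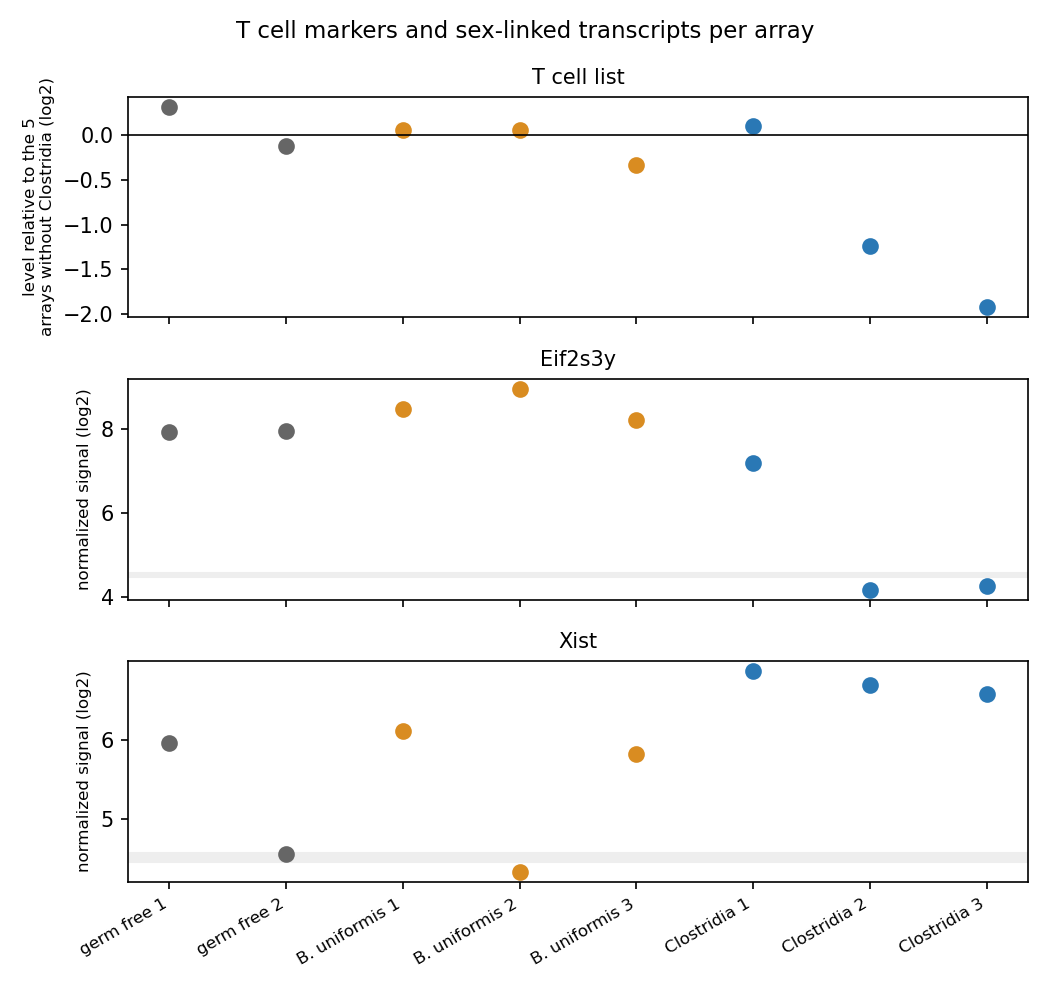
Mean log2 level of the T cell and intraepithelial lymphocyte list relative to the 5 arrays without Clostridia, and normalized log2 signal of Eif2s3y and Xist, for each array (points, coloured by group); the grey bands span the lowest detected signals of the arrays. The T cell list stands at -1.242 and -1.927, and Eif2s3y at 4.17 and 4.25, on Clostridia arrays 2 and 3.

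Without Clostridia arrays 2 and 3 together, which leaves 1 Clostridia array, the T cell list stood at 0.00 (adjusted p = 0.852), and its mean was -1.69 without Clostridia array 1, -0.67 without Clostridia array 3, -0.70 with no background correction and 0.40 with the Eif2s3y level as a covariate. The camera call of goblet cell genes was lost without germ free array 1 (adjusted p = 0.0935), germ free array 2 (0.193) or Clostridia array 1 (0.724), that of fatty acid oxidation without germ free array 2 (0.192) or Clostridia array 1 (0.0536), and that of the xenobiotic response without germ free array 1 (0.387), Clostridia array 3 (0.247) or B. uniformis array 3 (0.061). The goblet mean was -0.47 with the authors' values, -0.69 with the Eif2s3y covariate, -0.54 with the T cell covariate and -0.57 without Clostridia arrays 2 and 3 together. The goblet call was also lost with no detection filter (0.0751), the strict detection filter (0.0856) or array weights (0.056), and the xenobiotic call with no detection filter (mean 0.14, 0.121), the authors' values (0.0872), only the groups compared (0.0648), array weights (0.056), without Clostridia arrays 2 and 3 together (0.249), or with the Eif2s3y level as a covariate (mean 0.27, adjusted p = 0.178) or the T cell list level as a covariate (mean 0.20, 0.442).

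B. uniformis was compared with germ free mice to ask the same question of a single bacterium. The bile acid transport and FXR target list rose by a mean of 0.34, with 5 of 7 members higher (camera adjusted p = 0.0335, and adjusted p = 0.591 with an estimated correlation). Its leading members were Slc51a and Slc51b, the paired subunits of the basolateral bile acid transporter (1.09 ± 0.35 and 0.28 ± 0.20 SE), the bile acid receptor gene Nr1h4 (0.67 ± 0.30 SE) and the hormone gene Fgf15, which was not detected without bacteria and was at least 1.19-fold higher. Fgf15 was near the lowest detected signal with B. uniformis too, at 4.793, 4.463 and 4.926 on arrays 1, 2 and 3. On array 2 it lay below that array's lowest detected signal (4.516). Cholesterol synthesis and SREBP target genes fell by a mean of 0.23, with 17 of 21 members lower (camera adjusted p = 0.0431, and adjusted p = 0.885 with an estimated correlation). Among them were Nsdhl (-0.81 ± 0.50 SE), Mvd (-0.44 ± 0.32 SE), Scd2 (-0.35 ± 0.27 SE) and Fasn (-0.27 ± 0.19 SE). No member of either list passed on its own. The sucrase-isomaltase gene Sis, a small intestinal brush border enzyme, stood at 6.63 ± 0.74 (SD, n = 3) against 4.58 ± 0.08 (SD, n = 2), and was the only member of any list to pass for B. uniformis when adjusted over the list alone, of 6 tested members (limma adjusted p = 0.0328). Adjusted over the genes of all lists together, Sis did not pass (limma adjusted p = 0.991).

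Adjusted over all genes, limma called 0 genes between B. uniformis and germ free, with a smallest adjusted p of 0.583. At an unadjusted p under 0.05 there were 263 genes, 128 higher and 135 lower, where 455 are expected by chance, and 16.5% of genes had arrays that did not overlap, where chance gives 20%. Scn11a, at least 2.1-fold lower with B. uniformis and detected on both germ free arrays, had the smallest p, followed by Cracr2a (-1.25 ± 0.19 SE). Other low values were those of the transferrin receptor gene Tfrc (-0.96 ± 0.20 SE), Nudcd3 (at least 4.44-fold lower) and Ttpal (-1.68 ± 0.37 SE), whose other probe had the opposite sign. The higher genes of smallest p were the nuclear receptor gene Nr6a1 (1.27 ± 0.27 SE), Igfals (1.72 ± 0.39 SE), the glycine decarboxylase gene Gldc (at least 3.26-fold higher), AI597479 (0.97 ± 0.23 SE) and 2310011J03Rik (0.77 ± 0.18 SE). Reg3b stood at 7.35 ± 0.02 (SD, n = 3), a difference of 0.74 ± 0.26 (SE) that did not pass. Cyp2c55 differed by 0.09 ± 0.27 (SE) and Mcpt1 by -0.07 ± 0.18 (SE). Immediate early and dissociation stress genes averaged -0.15 (15 of 20 lower, camera adjusted p = 0.23), the T cell list -0.17 (11 of 15 lower, 0.792), goblet cell genes -0.14 (adjusted p = 0.411) and fatty acid oxidation genes 0.10 (adjusted p = 0.411).

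The bile acid call was lost whichever array of these groups was left out, with adjusted p of 0.171 and 0.242 without germ free arrays 1 and 2 and of 0.0559, 0.05004 and 0.0701 without B. uniformis arrays 1, 2 and 3. The cholesterol call was lost without germ free array 1 (0.192), germ free array 2 (0.242), B. uniformis array 2 (0.174) or B. uniformis array 3 (0.155). The bile acid call was also lost with median scaling (mean 0.06, adjusted p = 0.0633), no detection filter (mean 0.20, 0.457) or the strict detection filter (0.0734), and its mean was 0.54 with the authors' values. The cholesterol call was also lost with no background correction (mean -0.12, 0.108), normexp (mean -0.15, 0.0847), median scaling (mean -0.46, 0.0633), the authors' values (mean -0.43, 0.0699), no detection filter (0.103), the strict filter (0.182), array weights (0.127), the mean of a gene's probes (0.0527) or the Eif2s3y covariate (mean -0.14, 0.352). With each array scaled to the same median in place of quantile normalization, which moved the median of all genes by -0.228, the genes at an unadjusted p under 0.05 were 18 higher and 460 lower.

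Clostridia and B. uniformis were then compared directly, which asks whether the kind of bacterium matters. Cyp2c55 was higher with Clostridia by 2.16 ± 0.25 (SE), and the 3 Clostridia arrays lay above the 3 B. uniformis arrays. Mcpt1 was detected on the 3 B. uniformis arrays (5.61 ± 0.20, SD, n = 3) and on none with Clostridia, at least 2.15-fold lower. The metallothionein gene Mt2 was lower by -0.98 ± 0.20 (SE), the interferon-inducible gene Ifi27l2a was at least 1.58-fold lower and not detected with Clostridia, and the tight junction gene Marveld3 was higher by 1.06 ± 0.22 (SE). These 5 genes passed when adjusted over the list alone, with limma adjusted p = 0.000378 for Cyp2c55, 8.3e-05 for Mcpt1, 0.0185 for Mt2, 0.0368 for Ifi27l2a and 0.0182 for Marveld3. Adjusted over the genes of all lists together, Cyp2c55 and Mcpt1 passed, and Mt2, Marveld3 and Ifi27l2a did not (limma adjusted p = 0.122, 0.122 and 0.126). Reg3b differed by 0.86 ± 0.23 (SE) and did not pass (limma p adjusted over the list alone = 0.0929).

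By camera, 3 lists differed between the colonized groups. The T cell list fell by a mean of 0.95, with 15 of 15 members lower with Clostridia (adjusted p = 4.73e-07, and adjusted p = 0.605 with an estimated correlation), and Cd3e was measured at -1.56 ± 0.67 (SE) and Itgae at -1.49 ± 0.69 (SE). Immediate early and dissociation stress genes rose by a mean of 0.34, with 18 of 20 members higher (adjusted p = 9.74e-05, and adjusted p = 0.605 with an estimated correlation). They were led by the heat shock genes Hspa1a (1.14 ± 0.32 SE), Hspb1 (0.998 ± 0.26 SE) and Dnajb1 (0.60 ± 0.19 SE) and by Jun (0.50 ± 0.20 SE). The bile acid list fell by a mean of 0.46 (median -0.20), with 7 of 7 members lower (adjusted p = 0.0143, and adjusted p = 0.605 with an estimated correlation). Its leading members were Slc51a (-1.06 ± 0.31 SE) and the bile acid binding protein gene Fabp6 (-1.32 ± 0.49 SE).

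**Figure D3:**
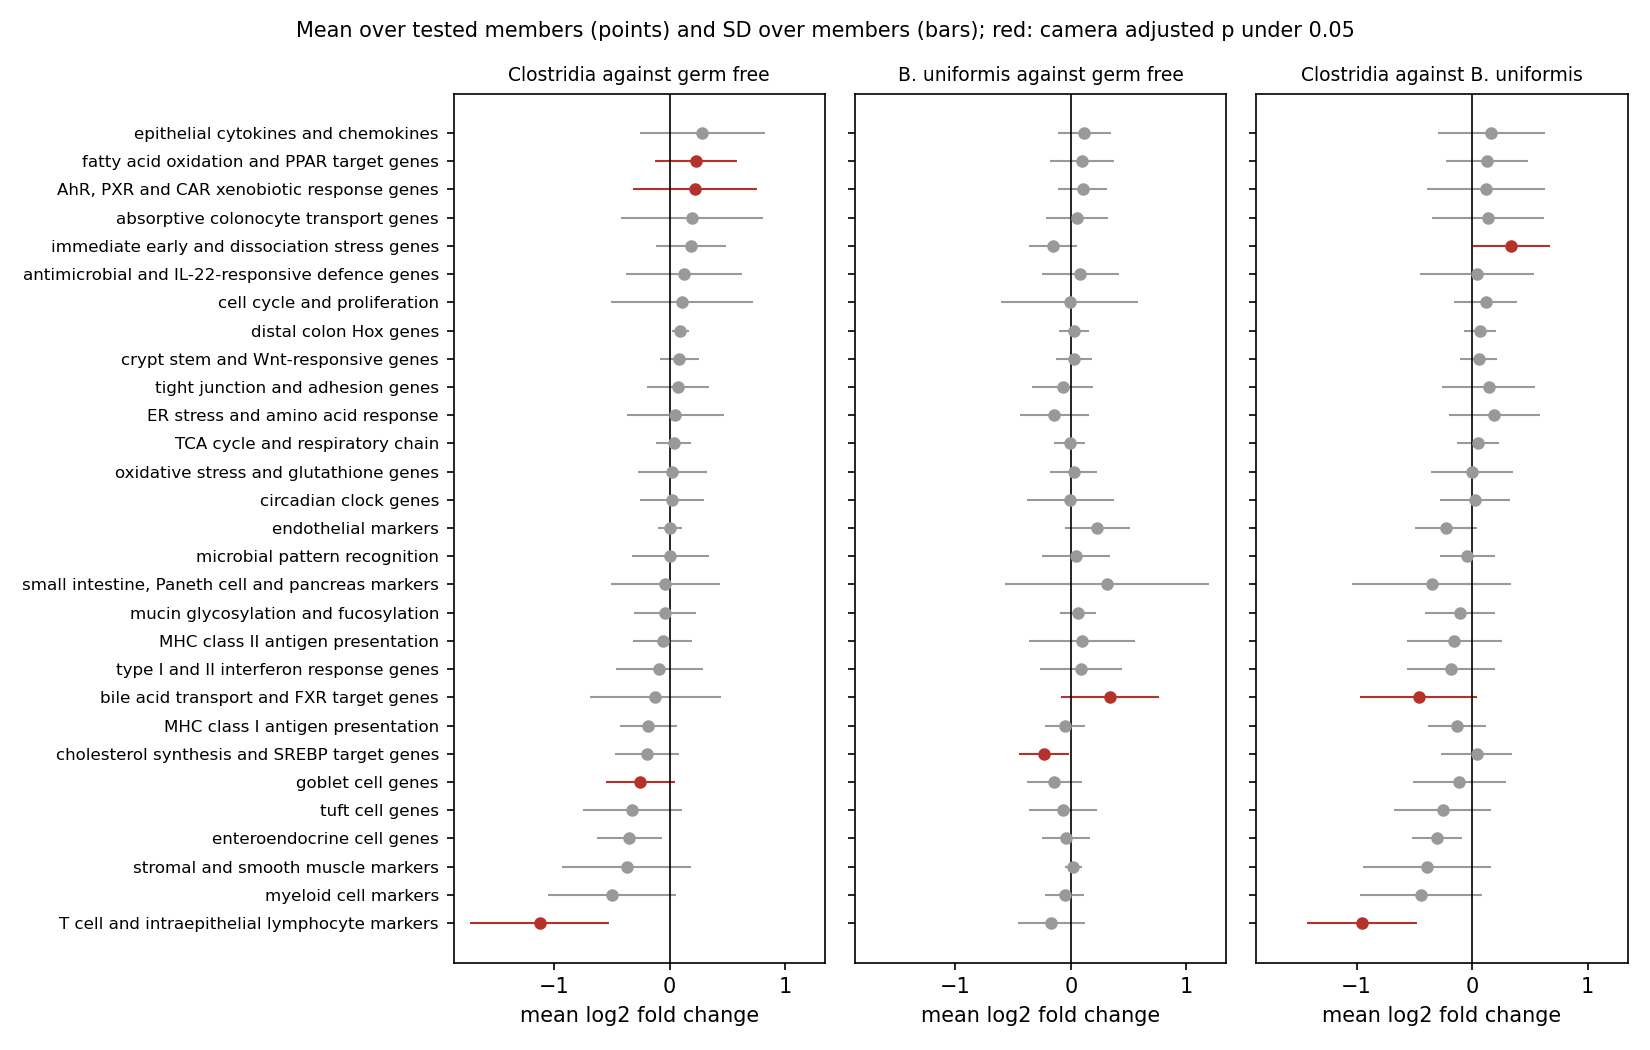
Mean log2 fold change over the tested members of each of the 29 tested gene lists (points) with the SD over members (bars) in the 3 comparisons, red where the camera adjusted p is under 0.05. The T cell list lies farthest from 0, at -1.12 and -0.95, in both comparisons that involve Clostridia, and at -0.17 between B. uniformis and germ free.

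Adjusted over all genes, limma called 0 genes between Clostridia and B. uniformis, with the smallest adjusted p at 0.126 for Cyp2c55 and Mcpt1. At an unadjusted p under 0.05 there were 445 genes, 256 higher and 189 lower, where 455 are expected by chance, and 8.89% of genes had arrays that did not overlap, where chance gives 10%. The next genes by p were Depp1 (1.31 ± 0.22 SE), Hoxa5 (1.05 ± 0.18 SE), Wfs1 (1.14 ± 0.21 SE) and Myl12a (1.17 ± 0.21 SE) on the higher side. On the lower side they were Myl1 (at least 2.07-fold lower), Limd2 (-0.89 ± 0.15 SE), Plpp1 (-0.97 ± 0.17 SE) and the T cell signalling gene Tespa1 (-1.60 ± 0.29 SE). Limma adjusted p for these 8 genes was 0.4 or 0.417. With median scaling, which moved the median of all genes by 0.263, the genes at an unadjusted p under 0.05 were 1195 higher and 31 lower, the bile acid mean was -0.13 and the immediate early mean was 0.67. Without Clostridia array 1 the genes were 328 higher and 369 lower. The T cell list stood at 0.17 without Clostridia arrays 2 and 3 together, which leaves 1 Clostridia array (adjusted p = 0.291), at -1.52 without Clostridia array 1, at -0.50 without Clostridia array 3, at -0.58 with no background correction and at 0.91 with the Eif2s3y level as a covariate. The immediate early call was lost without B. uniformis array 3 (mean 0.22, adjusted p = 0.0501), and its mean was 0.64 with the Eif2s3y covariate. The bile acid call was lost without Clostridia array 2 (adjusted p = 0.134), without Clostridia arrays 2 and 3 together (0.273), with no detection filter (mean -0.28, 0.226), with the T cell list level as a covariate (mean -0.40, adjusted p = 0.102) or with the Eif2s3y level as a covariate (mean -0.24, adjusted p = 0.699). Over the 3 comparisons, 0 of the 9 list calls held with an estimated correlation. Limma's fry found 0 lists shifted in one direction in each comparison, and lists changed in either direction numbered 2, 0 and 3 for Clostridia against germ free, B. uniformis against germ free and Clostridia against B. uniformis. The mean, the median and the direction of the test differed in sign for 3, 2 and 4 lists in the same order, none of them among the 9 calls. By fry in either direction, the lists for Clostridia against germ free were fatty acid oxidation and the xenobiotic response. Against B. uniformis they were the same 2 and oxidative stress, none of them called by camera there. The xenobiotic list holds Cyp2c55 and was not tested without it, so its fry result may rest on that gene. The 3 camera calls against B. uniformis did not pass it. Their fry adjusted p was 0.519 for the T cell, 0.28 for the immediate early and 0.519 for the bile acid list.

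The moderated F test of limma found 0 genes that differed between any of the 3 groups, with 353 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.166, for Cyp2c55. The colonization effects of Clostridia and of B. uniformis, both measured against the same 2 germ free arrays, correlated at r = 0.492 across genes, which are not independent replicates. Unchanged groups simulated against shared germ free arrays gave a mean r of 0.541, with a range of -0.753 to 0.977. The covariance was 0.0492, against a simulated mean of 0.0744, and 68.1% of genes had the same sign in both, against a simulated mean of 69.8%. With 1 germ free array for each comparison, r was -0.0972 and -0.0233. At an unadjusted p under 0.05, 41 genes were higher with both bacteria and 32 lower. Unchanged groups simulated with the same shared germ free arrays gave at least as many in 32 and 33 of 100 runs, and at an adjusted p under 0.05 the overlap was 0. The germ free arrays were too few to split into sets of at least 2.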

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

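The covariate tests, the count of T cell markers and the level of Clostridia array 1 were chosen only after the results had been seen, whereas the splits of the arrays were planned. The 8 results below passed in the direct comparison of the colonized groups, by camera for lists and by limma adjusted over the list alone for genes. With an estimated correlation the 3 lists did not pass (adjusted p = 0.605 for each), and adjusted over the genes of all lists together Mt2, Marveld3 and Ifi27l2a did not (0.122, 0.122 and 0.126).

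The T cell and intraepithelial lymphocyte list was lower with Clostridia than with B. uniformis by a mean of -0.95. On both Clostridia arrays 2 and 3, 11 of 15 members lay below each of the 5 arrays without Clostridia, but these arrays were singled out by that low level, so the count decides nothing about fewer lymphocytes among their cells. With the Eif2s3y level as a covariate the list stood at 0.396 against germ free. Sex of the animals stays open too, because the same 2 arrays lacked Eif2s3y. Y-linked Kdm5d was not detected there, and Uty was. Uty lay near the lowest detected signal on the 8 arrays (4.45 to 4.99). It was not detected on B. uniformis array 2, where Eif2s3y was highest (8.97), so Uty does not count against sex. Clostridia array 1 stood at 0.105, within the range of the arrays without Clostridia, so the list was not low on each colonized array, and colonization with Clostridia stays open for the other 2. For arrays 2 and 3, lymphocyte share and sex cannot be told apart. Rcsd1 and Sh2d2a, genes of lymphocytes chosen after their values were seen, were also lower on 2 arrays that have Eif2s3y. They stood at 6.77 and 6.36 on B. uniformis array 3 and at 8 and 7.97 on germ free array 2. On the remaining 4 arrays they ranged from 8.81 to 9.08 and from 8.57 to 9.23. Other lymphocyte genes went both ways on B. uniformis array 3. Ly9 stood there at 6.89 and Cd7 at 6.337, against 5.99 to 6.63 and 6.195 to 6.508 on those 4 arrays. Cd8b1 stood there at 4.42 and Itgae at 8.959, against 5.174 to 6.209 and 9.809 to 10.439. The T cell list as a whole stood at -0.327 there and at -0.121 on germ free array 2, against 0.06 to 0.324 on those 4 arrays. The list was thus somewhat lower on 2 arrays that have Eif2s3y, but far less so than on Clostridia arrays 2 and 3. Single genes chosen in this way decide nothing, and the list does not separate lymphocyte share from sex on Clostridia arrays 2 and 3.

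Cyp2c55 was higher with Clostridia by 2.16, Mcpt1 was lower by -1.33, a fitted value below detection like those that follow for it, and Reg3b went with them against germ free. With the Eif2s3y level as a covariate, 3 of 3 genes kept their sign against germ free at a limma unadjusted p under 0.05. The values were 2.94, -1.37 and 1.26 for Cyp2c55, Mcpt1 and Reg3b. Clostridia array 1 alone of its group had Eif2s3y, so the fit rests mainly on that array and cannot decide on sex. On it the 3 genes stood at 12.55, 4.31 and 7.938. The 5 arrays without Clostridia ranged from 9.674 to 10.02, from 5.47 to 5.837 and from 6.544 to 7.372 for the same genes. With the T cell list level as a covariate, 3 of 3 genes also kept their sign at that threshold (2.63, -1.39 and 1.27). This fit has the same limit, because the T cell list was low on Clostridia arrays 2 and 3 and not on array 1. T cell markers also do not measure mast cells, the source of Mcpt1, and the mast cell share was not tested. Mast cell and eosinophil markers, Mcpt1 among them, averaged -0.625, -0.808 and -0.686 on Clostridia arrays 1, 2 and 3. These levels are relative to the mean of the 5 arrays without Clostridia. Against B. uniformis, Reg3b stood at 0.44 with the Eif2s3y covariate (limma unadjusted p = 0.342) and at 0.58 with the T cell covariate (0.0521). Reg3b did not reach an unadjusted p under 0.05 in either fit. An effect of Clostridia on these genes is a candidate explanation. Sex of the animals, the share of other cells and, not analysed here, differences between cages or isolators stay open.

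The bile acid transport and FXR target list was lower with Clostridia than with B. uniformis by a mean of -0.46. Immediate early and dissociation stress genes were higher with Clostridia by a mean of 0.34. Mt2 was lower by -0.98 and Ifi27l2a by -0.91 on the fitted scale, and Marveld3 was higher by 1.06.

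The 6 colonized arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 0 genes, against a highest of 2 in the others. Because its count was 0, 10 of 10 splits had a count as large whatever the data, the real one included, which decides nothing. The real split called 3 lists, against a highest of 6, and 5 of 10 splits had as many. B. uniformis arrays 1 and 2 with Clostridia array 1, set against the other 3, gave 1134 genes at an unadjusted p under 0.05, where the real split gave 445 (limma), which points to a structure of the samples other than the groups.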

How the results depend on the processing

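The Eif2s3y and T cell covariates, leaving out Clostridia arrays 2 and 3 together and testing only the genes of the fixed lists were chosen after seeing the data. Gene counts of 0 held in 13 of 16 other settings for Clostridia against germ free, 16 of 16 for B. uniformis against germ free, 12 of 16 for Clostridia against B. uniformis and 13 of 14 for the F test. With limma's trend and robust options, 1 gene passed in each of the last 2 and in Clostridia against germ free (Cyp2c55). With only the genes of the fixed lists, 3 genes passed for Clostridia against germ free (Cyp2c55, Mcpt1, Reg3b) and 2 against B. uniformis (Cyp2c55, Mcpt1), since fewer genes were tested. Without Clostridia arrays 2 and 3 together the counts were 2 (Alas2, Slc30a10) and 1 (Alas2), and with the Eif2s3y covariate 1 (Alas2) against B. uniformis. With each array left out in turn, counts ranged from 0 to 2 for Clostridia against germ free, 0 to 5 for Clostridia against B. uniformis and 0 to 3 for the F test. Without germ free array 1, 2 genes passed against germ free (Cops8, Mcm6), without Clostridia array 1 there were 1 (Eif2s3y), 5 against B. uniformis and 3 by F test, and without Clostridia array 2 there were 1 (Slc30a10), 2 and 1. Where 1 germ free or 1 Clostridia array was left, it was assumed to vary like the other groups.

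For lists, Clostridia against germ free went from 4 to 2 with array weights, 9 at an adjusted p under 0.1, 7 with the Eif2s3y covariate, 0 with an estimated correlation, 0 by fry in one direction and 2 by fry in either direction, and to 3 to 6 with 1 array left out. B. uniformis against germ free went from 2 to 1 with no background correction, normexp with offset 50, the authors' values, array weights or the mean of a gene's probes. It went to 0 with median scaling, no detection filter, the strict detection filter, an estimated correlation and fry of either kind, and to 0 to 2 with 1 array left out (0 without either germ free array, 1 without B. uniformis array 1 or 2). The 1 list without B. uniformis array 2 and the 2 lists without B. uniformis array 3 were other lists than bile acid and cholesterol. Neither of the original calls held there, so an equal count does not mean equal calls. Clostridia against B. uniformis went from 3 to 13 with median scaling, 7 with array weights, 5 at an adjusted p under 0.1, 6 with the Eif2s3y covariate, 5 with the T cell covariate, 5 without Clostridia arrays 2 and 3, 0 with an estimated correlation, 0 by fry in one direction and 3 to 7 with 1 array left out (7 without Clostridia array 1, 6 without B. uniformis array 3). Median scaling moved the median of all genes by 0.0419, -0.228 and 0.263 in the 3 comparisons. The T cell list reversed with the Eif2s3y covariate (0.396 against germ free, 0.909 against B. uniformis) and no longer passed without Clostridia arrays 2 and 3 (0.00375 and 0.173, adjusted p = 0.852 and 0.291). The agreement of both colonization effects fell from r = 0.492 to 0.00931 with the Eif2s3y covariate, reversed to -0.0972 and -0.0233 with a single germ free array for each comparison, and ranged from 0.4002 to 0.692 with 1 array left out (0.665 and 0.692 without germ free array 1 or 2). Unless a reason is given, the cause was not tested. Of 5701 values of named genes under the alternatives, 173 had the other sign and 13 passed the threshold. The slide was not run as a block because the headers give no slide, and no paired analysis was run because the labels give no replicate number shared between groups. With an upper quartile of 1.32 to 1.66 times the background, dim genes have compressed fold changes.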

Other observations

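The tests of Xist and Eif2s3y were chosen only after the result had been seen, and the genes named outside the lists were chosen after their values were seen. Of the lists not yet described, none passed by camera in any comparison. With Clostridia against germ free, enteroendocrine genes averaged -0.35 (10 of 11 lower, camera adjusted p = 0.0901), tuft cell genes -0.32 (7 of 9 lower, 0.231) and cholesterol synthesis genes -0.19 (16 of 21 lower, 0.0533). MHC class I genes averaged -0.18 (11 of 14 lower, 0.0901), epithelial cytokines 0.28 (10 of 15 higher, 0.176), antimicrobial genes 0.12 (10 of 18 higher, 0.508) and colonocyte transport genes 0.19 (10 of 16 higher, 0.798). Interferon response genes averaged -0.18 between Clostridia and B. uniformis (17 of 25 lower, 0.0562). Means against germ free, for Clostridia and then B. uniformis, were -0.06 and 0.09 for MHC class II, 0.00 and 0.05 for pattern recognition, 0.11 and -0.01 for the cell cycle, 0.09 and 0.03 for crypt stem genes, and 0.04 and -0.01 for the TCA cycle and respiratory chain. They were 0.05 and -0.14 for ER stress, -0.04 and 0.07 for mucin glycosylation, 0.07 and -0.07 for tight junctions, 0.02 and 0.02 for oxidative stress, 0.02 and -0.00 for the circadian clock, and 0.09 and 0.03 for distal Hox genes. Small intestine, Paneth cell and pancreas markers averaged -0.04 and 0.31. B and plasma cell markers (2 tested) averaged -0.47 and -0.31, mast cell and eosinophil markers (3 tested) -0.78 and -0.13, red blood cell markers (3 tested) 0.94 and -0.08, and no marker of enteric neurons and glia passed the detection filter.

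Slc30a10, a manganese transporter gene, stood at 8.61, 6.19 and 8.12 on Clostridia arrays 1, 2 and 3 and between 4.98 and 5.53 on the other 5. It did not pass with all arrays and passed without Clostridia array 2 (3.38 against germ free, limma adjusted p = 0.0188). The heme synthesis gene Alas2 stood at 9.20 and the globin gene Hba-a1 at 12.31 on Clostridia array 1, against 4.98 to 5.52 and 7.10 to 9.65 on the other 7. Mcm6 and Cops8 stood at 4.26 and 4.82 on germ free array 2, against 8.12 to 8.99 and 7.68 to 8.54 on the others. Mcm6 had another probe without this drop, which gave -0.14 for Clostridia against germ free with the strict detection filter. Ang4 ranged from 6.43 to 9.49 and its levels did not follow the groups.

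Xist, a transcript of the inactive X chromosome, and the Y-linked Eif2s3y were both detected at p under 0.01 on 4 arrays: germ free 1, B. uniformis 1 and 3, and Clostridia 1. This is in line with RNA from animals of both sexes in 1 sample, which may mean pooled colons. Unspecific signal of the Xist probe stays open: 1 array with Eif2s3y, B. uniformis 2, had Xist at a detection p of 0.05 or more (0.178), and germ free 2 had it at 0.0288. A second Xist probe was not detected on any array at p under 0.05 (lowest 0.0514). Xist alone was detected on Clostridia arrays 2 and 3 (6.69 and 6.57).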
